A study of Nitrososphaera viennensis EN76 with 4 samples.

How the data were processed

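RNA-seq libraries of total RNA were made from Nitrososphaera viennensis EN76 grown at 33 °C (2 libraries) and 42 °C (2 libraries). Per the labels' protocols, RNA was isolated with TRIzol and libraries followed standard Illumina protocols. The submitters' processing notes name HISAT2 (a read aligner), HOMER (a toolkit that can count reads per gene) and DESeq2 (a test on counts), with no version, role or order. The genome build, the annotation, the strand setting of the counting and any filter are not given in the sources used here.

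The authors deposited 1 table for the series with a read count per gene and library. The deposited file is named for RPKM, but its columns hold whole numbers that rise with gene length (Spearman correlation of 0.37 to 0.55 per library) and sum to different totals, so they were treated as raw counts. Per the file headers the table gives each gene an identifier, start, end, width and strand. Gene lengths were multiples of 3 in 2821 of 2836 rows, so most are likely coding lengths. The rows were numbered up to 2882, and 46 of these numbers do not occur among the rows used here. The table names no ribosomal or transfer RNA, and 1 gene has no strand. In 430 neighbouring pairs the genes overlap, 169 of them on opposite strands. Of the 2836 genes 775 overlap a neighbour, and of the 281 changed genes 69 do, 23 of these with an opposite-strand neighbour. Reads in an overlap on 1 strand cannot be told apart by strand. Those in an opposite-strand overlap can be only where the counting used strand. Each of the 4 columns matched 1 sample by name, and 0 columns of other samples were present.

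Samples were grouped by temperature from their titles. The test first planned for this series was limma on log2(RPKM + 1). Because the values are counts, edgeR's quasi-likelihood test was used in its place, as laid down before the data were examined for the case of counts. The test used edgeR 4.0.16 in R 4.3.3, with filterByExpr (which kept all 2836 genes), TMM normalization, all 4 libraries and temperature as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The SE of a log2 change was taken as its size divided by the square root of the F statistic. Levels are TMM-normalised CPM (counts scaled to the effective library size), given as mean ± SD of 2 libraries. An exact permutation test of 2 against 2 libraries cannot go below p = 0.33, so single genes were tested with models that pool the spread across genes (edgeR, and limma and DESeq2 as alternatives). Where 1 library was left out, the lone library was assumed to vary like the pair of the other temperature. The estimated biological coefficient of variation was 28.7%. On simulated data with the spread estimated from these libraries, 33% of 100 genes changed by 2-fold and 85% of 100 genes changed by 4-fold were recovered among 2836 genes, with 6 unchanged genes among the 124 called. The simulated genes were independent and had the same spread at both temperatures. They held no shift between replicates by expression level and no correlation of neighbours, both seen in these libraries. The simulated rates may therefore not hold for the calls made here. Totals of 11574637 to 15339183 counted reads left counting error small against the spread between libraries for most genes. The replicates of a temperature were not the same library deposited again: a chi-square test of their counts gave 349 per degree of freedom for 33 °C and 312 for 42 °C.

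The genes named in the text followed a rule fixed before the data were examined: where no product names are given, the 2 genes with the largest rise and the 2 with the largest fall among changed genes whose groups do not overlap and whose mean RPKM reached 10 in the higher group, and every tfb gene. The other 6 genes with a symbol and the gene with the most reads were added after the data were seen. Of 34 gene lists fixed as text patterns for gene names, 1 found any member in the table, that of RNA polymerase and general transcription factors, with the 4 tfb genes; the pattern does not match rpoH. Lists of ammonia oxidation, chaperones, chromatin proteins and the other 30 are therefore not analysed here. The list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Neighbouring genes were compared by the correlation of their log2 changes against 10000 shuffled gene orders. Runs of at least 4 adjacent called genes, segments of 100 kb and 5 classes of expression were chosen after the data were seen.

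Alternatives laid down beforehand were pseudocounts of 0.1 and 5 in limma on log2 RPKM, quantile normalization, no filter and a filter at an RPKM of 10, centring on the median gene, leaving out each library, a replicate block, fits without an abundance trend and with a robust fit, DESeq2 1.42.0, and other thresholds. Added after the data were seen were limma with a pseudocount of 1, total-count scaling, DESeq2 size factors in edgeR, a fit without the gene with the most reads, and subtraction of a read background in proportion to gene length, set at the lowest or the 1st percentile of reads per kb in each library (for the expression classes also at the 5th and 10th). Limma with a pseudocount of 1 was the main test first planned, and only its use as an alternative was added later. Rescaling without ribosomal and transfer RNA had no rows to remove and was not run. Replicates share a number across temperatures, but no source says that a number marks a shared culture, day or batch, so the main test has no replicate block.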

Results

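Gene expression was measured by RNA sequencing of total RNA from Nitrososphaera viennensis EN76, a soil archaeon that lives by oxidising ammonia, grown in the dark in freshwater medium at 33 °C or at 42 °C. Changes are given as 42 °C over 33 °C, and neither temperature is treated here as a stress or a control. There were 2 libraries per temperature, and nothing in the labels says that they came from separate cultures, so the p-values measure only the spread between these libraries. The table held read counts for 2836 genes between positions 1439 and 2527850, in coordinates whose genome build is not given in the sources used here. Counted reads came to 15339183 and 13559422 in 33 °C replicates 1 and 2, and to 11574637 and 11585187 in 42 °C replicates 1 and 2. Every gene had reads in every library, and the lowest count of any gene was 54, 20, 9 and 4 in the same order. Of the 2836 genes, 10 carried a symbol and 2826 a locus tag alone, so most genes are described here by position and group.

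The library of 33 °C replicate 1 stood apart from the other 3. Genes with little expression took more reads in it: the 1st percentile of genes lay at an RPKM (reads per kb of gene, scaled to library size) of 28.4 in 33 °C replicate 1, against 12.1 in 33 °C replicate 2, 8.62 in 42 °C replicate 1 and 4.99 in 42 °C replicate 2. Across genes, 33 °C replicate 2 correlated with its own replicate at r = 0.957 (Spearman 0.949) and with the libraries of 42 °C at r = 0.961 and 0.970 (Spearman 0.960 and 0.971). The 42 °C replicates correlated with each other at r = 0.987 (Spearman 0.988). Genes are not independent replicates, and these values describe the libraries without a test. The SD of the log2 difference between libraries was 0.71 within 33 °C and 0.44 within 42 °C, and it ranged from 0.65 to 1.17 across temperatures. A single gene of 2589 bases at 1427444 to 1430032 on the minus strand took 11.9% and 5.57% of the counted reads at 33 °C and 1.505% and 4.66% at 42 °C. Its log2 change at 42 °C was -1.22 ± 0.61 (SE), with an edgeR adjusted p of 0.20.

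**Figure D1:**
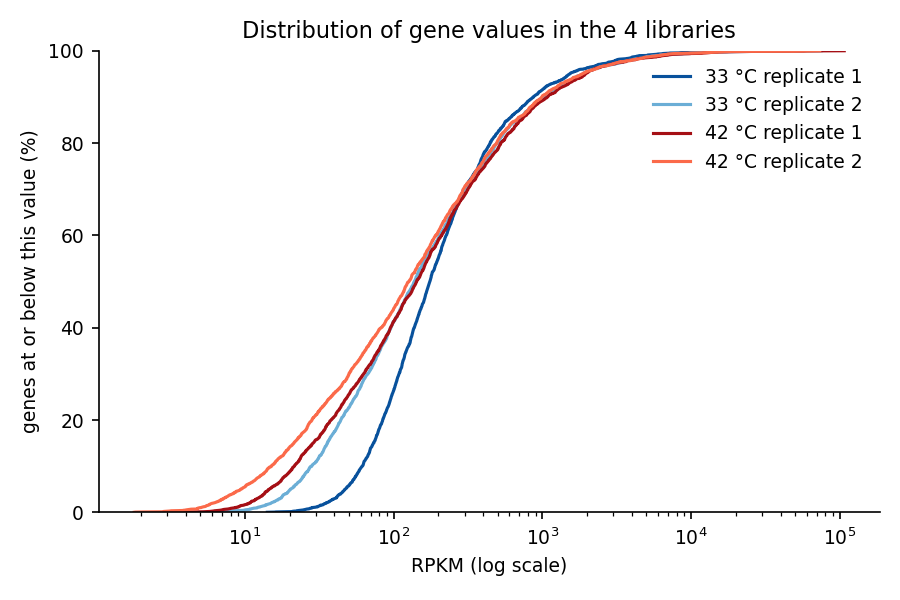
Cumulative share of the 2836 genes (y axis, percent) at or below a given RPKM (x axis, reads per kb of gene scaled to the total of each library, log scale), with 1 line per library. The line of 33 °C replicate 1 starts to the right of the others, with its 1st percentile at 28.4 against 4.99 to 12.1 in the other 3 libraries, and the lines meet among highly expressed genes.

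The main comparison asked which genes differed in transcript level between 42 °C and 33 °C. At 42 °C 121 genes were higher and 160 were lower, together 9.91% of the genes tested, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 104 of the higher and 159 of the lower genes changed by at least 2-fold, and all 281 had both libraries of one temperature above both of the other. Such separation was seen in 62.8% of all genes, where chance gives 33.3% for 2 against 2. Genes are not independent, and a shift between libraries that many genes share can raise this share. The gap to 33.3% therefore does not measure how many genes responded to temperature. The median log2 change of all genes was -0.01, with quartiles at -0.67 and 0.37. Among the 160 lower genes, 130 were higher in 33 °C replicate 1 than in replicate 2, with a median ratio of 2.48 over all 160. The size of the falls thus leaned on the library that stood apart. Among the 121 higher genes, 92 were higher in 42 °C replicate 1 than in replicate 2, with a median ratio of 1.32. Leaving out any library but 33 °C replicate 2 lowered the number of calls to a similar total: 114 without 33 °C replicate 1 (56 higher and 58 lower, of which 48 and 51 were among the genes called with all libraries), 112 without 42 °C replicate 1 (31 and 81) and 119 without 42 °C replicate 2 (77 and 42). The fit without 33 °C replicate 2 gave 678 (186 and 492). A fit without 1 library leaves 1 temperature with a single library and takes the spread from the pair of the other temperature alone, so a call kept without 33 °C replicate 1 rests on the spread of the closer 42 °C pair and is no separate replicate check. The balance of calls depended on the fit. With libraries centred on their median gene 136 genes were higher and 362 lower, so that the lower calls grew more than the higher ones. Scaling to total counts gave 16 higher and 33 lower and moved the median of all genes to -0.23. Higher genes outnumbered lower ones with a robust fit (119 and 97) and without an abundance trend (89 and 81).

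The largest fall was that of NVIE_RS08960, a gene of 183 bases at 1570701 to 1570883 on the minus strand. Its level was 416 ± 157 CPM (counts scaled to library size) at 33 °C and 19.5 ± 5.33 at 42 °C (SD, n = 2 each), 21.3-fold lower, with a log2 change of -4.41 ± 0.35 (SE) and an edgeR adjusted p of 1.1e-05. NVIE_RS04835, at 842464 to 843156 on the plus strand, fell 12.6-fold, from 1046 ± 324 to 83.1 ± 20.2 CPM (SD, n = 2 each), with an edgeR adjusted p of 3.0e-05. The largest rise was that of NVIE_RS07055, at 1234572 to 1235267 on the plus strand, which was 8.78-fold higher at 42 °C with an edgeR adjusted p of 0.0031. Its 42 °C libraries differed widely, at 3112 CPM in replicate 1 and 774 in replicate 2, against 191 and 252 at 33 °C. Without 42 °C replicate 1 its log2 change was 1.73 against 3.13 with all libraries, below the 2.37 of NVIE_RS07040 in the same fit. NVIE_RS07040 also had the larger rise without 33 °C replicate 1 (3.01 against 2.95) and with a replicate block (2.94 against 2.82). The same order held in limma on log2 RPKM at each pseudocount and after quantile normalization. In the remaining fits NVIE_RS07055 rose more. NVIE_RS07040, at 1233413 to 1233814 on the minus strand, rose 8.13-fold, from 581 ± 5.11 to 4722 ± 2203 CPM (SD, n = 2 each), with an edgeR adjusted p of 0.00062. All 4 of these genes were also called without 33 °C replicate 1, with the spread of the 42 °C pair. With total-count scaling NVIE_RS07055 had an adjusted p of 0.064.

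The table names 4 tfb genes, which code for transcription factor B, the archaeal counterpart of eukaryotic TFIIB that brings RNA polymerase to promoters. The tfb gene at 1039505 to 1040410 on the plus strand rose 3.76-fold at 42 °C, from 6244 ± 1664 to 23450 ± 8520 CPM (SD, n = 2 each), with a log2 change of 1.91 ± 0.47 (SE) and an edgeR adjusted p of 0.024. The other three did not pass the test with all libraries. The tfb gene at 152458 to 153354 had a log2 change of 0.40 ± 0.38 (SE), that at 1655282 to 1656172 of 0.80 ± 0.33, and that at 1683684 to 1684601 of -0.45 ± 0.34, with edgeR adjusted p of 0.52, 0.12 and 0.40. The gene at 1655282 had a log2 change of 1.26 and an edgeR adjusted p of 0.039 without 42 °C replicate 2, and a log2 change of 0.04 without 42 °C replicate 1. The gene at 1039505 held 57.9% and 58.2% of the reads of the 4 tfb genes at 33 °C, and 83.9% and 73.9% at 42 °C. Copies of one gene family can share reads, and how the authors assigned such reads is not given in the sources used here. Adjusted over the list alone, 1 of the 4 tfb genes was higher and 0 lower, as over all genes. The list of RNA polymerase and general transcription factors consisted of these 4 genes and had a mean log2 change of 0.66; camera with a preset correlation gave p = 0.048, and the call was lost with an estimated correlation (p = 0.20). The call of the gene at 1039505 depended on the fit and was lost in 8 of 20 alternatives, with log2 changes there from 1.41 to 1.77. Its edgeR adjusted p was 0.11 without 33 °C replicate 1, 0.13 without 42 °C replicate 1, 0.10 with total-count scaling and 0.054 after subtraction of the 1st percentile of reads per kb. The limma adjusted p on log2 RPKM was 0.11 at each pseudocount and 0.066 after quantile normalization.

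The table gave 6 further genes a symbol, and ychF alone among them passed the test. It codes for a conserved ATPase of the Obg family and was 2.02-fold higher at 42 °C, at 518 ± 2.61 against 256 ± 43.4 CPM (SD, n = 2 each), with an edgeR adjusted p of 0.032. Without 33 °C replicate 1, 42 °C replicate 1 or 42 °C replicate 2 its log2 change was 0.85, 0.95 or 1.01, against 1.02 with all libraries, and its edgeR adjusted p was 0.14, 0.15 or 0.14. The call was also lost with total-count scaling (edgeR adjusted p 0.092), after subtraction of the 1st percentile of reads per kb (0.065), and in limma on log2 RPKM (0.056 to 0.060, and 0.071 after quantile normalization). The rfc gene, for a subunit of the replication clamp loader, had a log2 change of 0.56 ± 0.27 (SE) and an edgeR adjusted p of 0.19. Log2 changes lay between -0.23 and 0.25 for leuD (leucine synthesis), pyrG (CTP synthase), aspA and rpoH (in archaea, a small subunit of RNA polymerase), with edgeR adjusted p from 0.59 to 0.85. A p above the threshold does not show that these genes kept their level, since each SE was between 0.27 and 0.32.

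**Figure D2:**
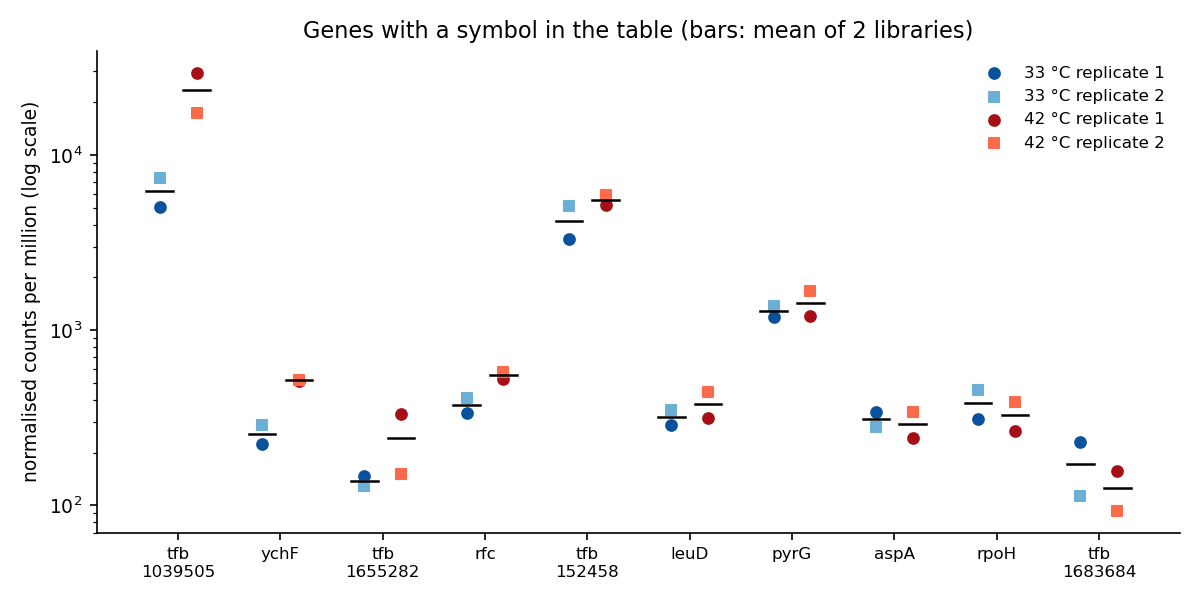
Normalised CPM (y axis, log scale) of the 10 genes with a symbol in each of the 4 libraries, with circles for replicate 1, squares for replicate 2 and bars for the mean of 2 libraries; tfb genes carry their start position. The tfb gene at 1039505 (6244 against 23450 CPM) and ychF (256 against 518) passed the edgeR test.

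The series title names a chromatin-driven mechanism of transcription, so the changes were also followed along the genome. Neighbouring genes changed together: the log2 change of a gene correlated with that of the next gene at r = 0.37 (Spearman 0.33, across 2835 pairs of genes). For 1703 pairs on one strand r was 0.44 (Spearman 0.40), and for 1130 pairs on opposite strands it was 0.26 (Spearman 0.24). In a two-sided permutation test of 10000 shuffled gene orders each of these 6 correlations had p = 1e-04, the smallest the shuffles can give, and an adjusted p of 1e-04. Genes are not independent replicates. The correlation fell with distance, to 0.13 for genes 5 places apart, 0.08 for 10 places and 0.01 for 50 places. Differences between replicates had the same property: between 33 °C replicates 2 and 1 neighbouring genes correlated at r = 0.39, and between 42 °C replicates 2 and 1 at r = 0.29.

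The changed genes included 10 runs of at least 4 adjacent genes called in the same direction. In 10000 shuffles of single calls there were at most 2, but such shuffles break the correlation of neighbours, which replicates showed too, so the number of runs is no evidence beyond that correlation. The minimum of 4 genes was set after the data were seen. There were 7 runs of lower genes, holding 33 genes, and 3 runs of higher genes, holding 13. The run with the strongest fall lay at 1003870 to 1007693 and held 4 plus-strand genes, whose summed level was 2021 ± 224 CPM at 33 °C and 274 ± 37.0 at 42 °C (SD, n = 2 each), 7.38-fold lower. The log2 changes of its genes were close together, from -3.03 to -2.84, and all 4 were also called without 33 °C replicate 1. Between 779776 and 850177 lay 4 runs of 5 plus-strand genes each. Their summed levels were 4.69-fold lower at 779776 to 788102, 4.16-fold lower at 801598 to 808361, 3.40-fold lower at 831610 to 836542 and 4.87-fold lower at 846393 to 850177. The run at 801598 was high in 33 °C replicate 1 alone, at 943 CPM against 275 in 33 °C replicate 2 and 177 and 116 at 42 °C, and 0 of its 5 genes stayed past the threshold without that library. Of the genes at 779776, 831610 and 846393, 1 of 5, 5 of 5 and 3 of 5 stayed past it. Calls were lost there although 33 °C replicate 2 itself lay well above 42 °C, at 784 CPM against 199 and 187 for the run at 779776 and at 253 against 69.9 and 46.0 for that at 846393. The remaining lower runs were 4 genes on both strands at 1045869 to 1050993, at 530 ± 65.3 CPM at 33 °C and 143 ± 18.4 at 42 °C, and 5 plus-strand genes at 1849505 to 1853248, at 1802 ± 352 and 606 ± 321 (SD, n = 2 each). Over all lower runs 21 of 33 genes stayed past the threshold without 33 °C replicate 1.

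The strongest run of higher genes lay at 1233413 to 1235267 and held 4 genes, of which the left pair is on the minus strand and the right pair on the plus strand, so that they diverge from a shared middle. NVIE_RS07040 and NVIE_RS07055 are its outer members. Its summed level was 1717 and 1898 CPM at 33 °C and 18712 and 7877 at 42 °C, 7.36-fold higher, with log2 changes of its genes from 2.54 to 3.13. At 1774735 to 1778290 a run of 5 genes on both strands was 2.92-fold higher, at 849 ± 21.4 CPM at 33 °C and 2478 ± 162 at 42 °C (SD, n = 2 each). At 2333268 to 2335450 a run of 4 genes was 3.34-fold higher, at 141 ± 0.525 and 472 ± 169 CPM (SD, n = 2 each). Without 33 °C replicate 1, with the spread of the 42 °C pair alone, 12 of the 13 genes in the higher runs were called, and there were 3 runs of higher and 3 of lower genes. After subtraction of the 1st percentile of reads per kb as a background there were 2 of each, and the run at 1849505, which had 5 of 5 genes called without 33 °C replicate 1, had 1 of 5.

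Lower genes were unevenly spread over the genome. Of 26 segments of 100 kb, the segment from 800 to 900 kb held 24 lower genes of 104, where the mean was 6.15 per segment. Shuffling blocks of 10 adjacent genes gave a median of 15 for the fullest segment (permutation p = 0.0062, one-sided). The correlation of log2 changes reached beyond such blocks, at 0.08 for genes 10 places apart and 0.06 for 20 places. The shuffles also did not hold expression fixed, so the p-values from them may be too small. Genes from 800 to 900 kb also had low expression, with a median of 45.8 CPM, and their median log2 change was -0.77. Without 33 °C replicate 1 this segment held 15 lower genes (permutation p = 0.013, one-sided). Higher genes numbered at most 11 in a segment, from 1700 to 1800 kb, where the shuffled median was 10 (permutation p = 0.41, one-sided).

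**Figure D3:**
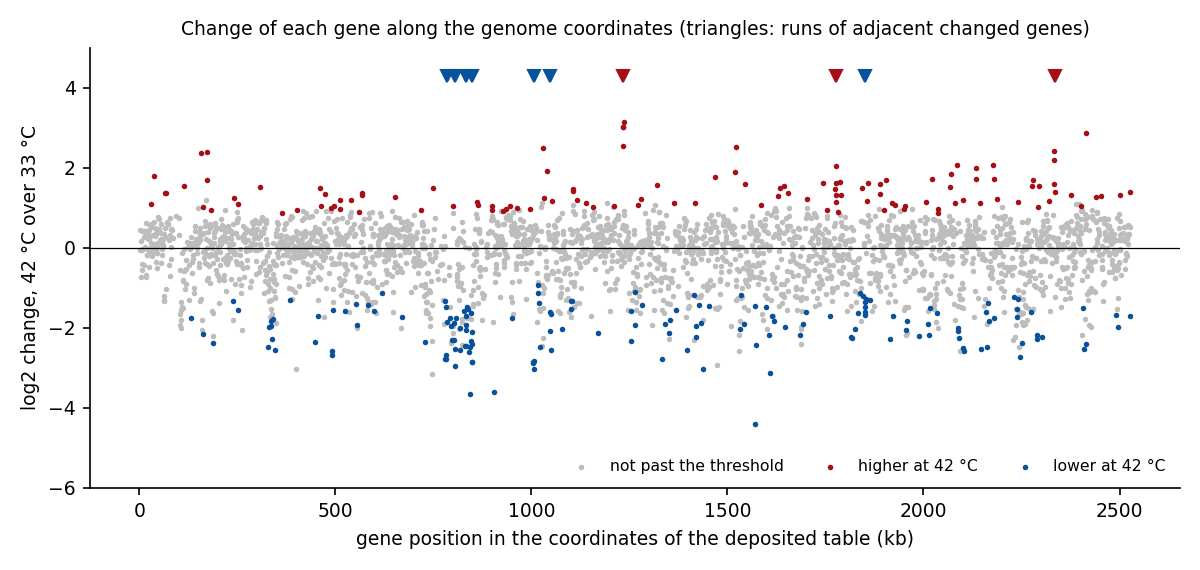
Log2 change at 42 °C over 33 °C of each of the 2836 genes (y axis) by its position in kb in the coordinates of the deposited table (x axis), with 121 higher genes in red, 160 lower genes in blue and the rest in grey. Triangles mark the 3 runs of higher genes in red and the 7 runs of lower genes in blue, 4 of which lie between 779776 and 850177.

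The direction of change went with the level of expression. When genes were split into 5 classes of equal size by their mean level over all libraries, the lowest class had 2 higher and 49 lower genes and a median log2 change of -1.003, and the next had 8 higher and 62 lower genes and a median of -0.40. The highest class had 41 higher and 3 lower genes and a median of 0.25. The same order appeared between replicates: from 33 °C replicate 1 to replicate 2 the lowest class had a median log2 difference of -0.995 and the highest 0.31. From 42 °C replicate 1 to replicate 2 these were -0.40 and 0.11. Without 33 °C replicate 1 the temperature difference of the lowest class was -0.40 and that of the highest 0.14, and 4 of the 49 falls of the lowest class stayed past the threshold.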

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

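No call of the 281 genes changed sign in any fit. All 281 had both libraries of 1 temperature above both of the other, so leaving out a library could hardly change a sign. The number of calls depended on the fit, and the cause was not tested unless given. The total of 281 (121 higher, 160 lower) became 465 with DESeq2 (287 lower), 498 centred on the median gene (362 lower), 49 with total-count scaling (16 and 33), 170 without an abundance trend (81 lower), 97 lower with a robust fit, 533 at an adjusted p under 0.1 (197 and 336) and 74 with a test against a 1.5-fold change (31 and 43). With limma on log2 RPKM it was 118 at a pseudocount of 0.1 (56 and 62), 115 at 1 (54 and 61), 104 at 5 (46 and 58) and 89 after quantile normalization (41 and 48). Subtracting a background gave 162 at the lowest reads per kb (79 and 83) and 67 at the 1st percentile (30 and 37). Leaving out 1 library gave 112 to 678 genes, 31 to 186 higher and 42 to 492 lower; the highest counts came without 33 °C replicate 2, when the outlying 33 °C library stood alone. A replicate block gave 699 genes (220 and 479), and the deviations of same-numbered libraries correlated at 0.43; with no stated pairing this says nothing on the size of the effect. The 281 calls were all among those 699. The median log2 change of all genes was -0.23 with total-count scaling and with limma at pseudocounts of 0.1 and 1 (-0.235, -0.232 and -0.232), and -0.226 at 5. The filter on low counts removed no gene and tests nothing. The correlation of neighbouring genes stayed past its threshold in all alternatives run.

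The mean log2 change of the tfb list stayed positive, but its p was above 0.05 in several fits. It was 0.66 with an estimated correlation (camera p = 0.20) and with fry (fry p = 0.19). By camera it was 0.65 with the replicate block, 0.67 with DESeq2, 0.69 centred on the median gene, 0.43 in limma at each pseudocount (0.431, 0.431 and 0.433), 0.41 after quantile normalization, and 0.61 and 0.56 after subtraction of the lowest and 1st percentile background, all with p above 0.05. Without 1 library it was 0.23 to 0.92. The camera test of limma gave an adjusted p (over 1 list) of 0.0505, 0.17 and 0.17 without 33 °C replicate 1, 33 °C replicate 2 and 42 °C replicate 1, and 0.0019 without 42 °C replicate 2. Some genes that were not called changed sign. Without 1 library the log2 change ranged from -0.37 to 0.063 for aspA, from -0.017 to 0.40 for leuD, from -0.090 to 0.31 for pyrG, from -0.54 to 0.039 for rpoH and from -0.95 to 0.15 for tfb at 1683684. After quantile normalization leuD was at -0.12, pyrG at -0.20 and tfb at 152458 at -0.044. For pyrG limma gave -0.0701, -0.0700 and -0.0696 at pseudocounts of 0.1, 1 and 5, and total-count scaling gave -0.060. The tfb gene at 1039505 passed the threshold in 12 of 20 alternatives (adjusted p from 5.0e-07 to 0.13) and ychF in 11 of 20 (0.0034 to 0.15). With 2 libraries per temperature the simulated recovery of 2-fold changes was 33%, which limits what a missing call can say.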

Other observations

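The tests of the background, of opposite-strand neighbours as 1 transcript and of short transcripts were chosen after the result they measure was seen; the other tests were set before. The genes that rose at 42 °C were short. Their median length was 384 bases, against 605.5 for all genes and 759 for the genes that fell, and 30.6% of them were under 300 bases, against 17.5% of all genes and 8.75% of the genes that fell. Without 33 °C replicate 1 the 56 rising genes had a median length of 363 bases. Of the genes that fell, 102 lay on the plus strand and 58 on the minus strand, and of the genes that rose 58 and 62; the strands hold 1368 and 1467 genes, and the difference was not tested, since neighbouring genes change together.

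High expression of short genes, taken as reads per kb, does not alone account for the length of the rising genes. The 10000 sets of other genes matched on reads per kb had a median length of 627 bases, with a central 95% from 537 to 738. None was as low as 384 (permutation p = 1e-04, one-sided, the smallest the sets can give). The sets were drawn gene by gene, while 24.0% of the rising genes lay next to another, so this p treats linked genes as independent. The expression classes were set by CPM, on which the sets were not matched. A difference between libraries in the recovery of short transcripts could move short genes as a group. Genes under 300 bases lay 0.05 below the others in median log2 change (-0.046, 95% bootstrap interval over genes from -0.16 to 0.07). Counts rose with gene length, though, and genes of low expression were called lower. An upward shift of short genes could be masked by this, so the comparison does not exclude such a difference. Counts also followed gene length more closely at 33 °C, with Spearman correlations of 0.55 and 0.42 in replicates 1 and 2. At 42 °C these were 0.37 and 0.38. Another hypothesis left open is that the rising set holds a class of short genes that responds to temperature, which the table cannot address because it gives these genes no product names.

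Genes of low expression were called lower and genes of high expression higher at 42 °C, and a read background that was larger at 33 °C, such as DNA left in the RNA, may contribute. Among the 40% of genes with the fewest reads per kb in 42 °C replicate 2, each other library was regressed on that library. The intercept was 57.7 in normalised RPKM in 33 °C replicate 1 (95% interval 50.4 to 65.0). It was 9.26 (-0.15 to 18.7) in 33 °C replicate 2 and 5.23 (3.81 to 6.66) in 42 °C replicate 1. The 1st percentile, before TMM scaling, was an RPKM of 28.4 in 33 °C replicate 1, below its intercept. In 33 °C replicate 2 and 42 °C replicate 1 it was 12.1 and 8.62, above theirs. Subtracting it would thus remove a background as large as the intercept only in part in 33 °C replicate 1. This subtraction left the lowest of 5 expression classes at -0.89 in median log2 change. Of 111 falls in the 2 lowest classes 13 stayed called. The median log2 change of the 111 went from -1.98 to -2.60 and their median SE from 0.51 to 0.70. Their median unadjusted p rose from 0.0023 to 0.0072 and the largest unadjusted p called fell from 0.0049 to 0.0011, so both the test and the cut-off moved. The 5th and 10th percentiles left the lowest class at -0.63 and -0.27, from -1.003 without subtraction, but the 10th left no reads in 38.6% to 42.3% of its genes in each library, which can pull the class toward 0 whatever the cause, so these values decide nothing. Without reads from between genes a background cannot be told apart from weak transcription that was higher at 33 °C. The order of the classes was not confined to 33 °C replicate 1. Without it the highest class still exceeded the lowest by 0.54 (95% bootstrap interval over genes 0.47 to 0.60). The 42 °C replicates differed by 0.51 in the same way. With all libraries the difference was 1.26, and how much of it came from 33 °C replicate 1 stays open.

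Neighbouring genes changed together, and opposite-strand neighbours correlated at r = 0.26 (permutation p = 1e-04, two-sided, 1130 pairs of genes). Where reads were counted by strand, 1 transcript covering genes of the same strand cannot be the whole account. The strand setting is not given, so a transcript that reaches into an opposite-strand gene is not excluded. Neighbours also had like expression (r = 0.36), but after removal of the trend of log2 change over expression the opposite-strand correlation was 0.15 (0.154, permutation p = 1e-04). The 327 opposite-strand pairs at least 200 bases apart correlated at 0.15 (0.152, permutation p = 0.0073), against 0.26 for all opposite-strand pairs. Reads shared at a junction may therefore account for part of the correlation. The gap and the removal of the trend were not combined, so shared reads and like expression together are not excluded. Without 33 °C replicate 1 the opposite-strand correlation was 0.19. The same correlation was 0.34 between the 33 °C replicates and 0.20 between the 42 °C replicates, so what changes regions together may not be specific to temperature, and a regional effect of chromatin, named in the series title, was not tested here.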
